A study of Mus musculus with 7 samples.

How the data were processed

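The series holds 7 sequencing libraries of RNA from the mouse macrophage line RAW264.7. Per the labels, RNA came from whole cells or from extracellular vesicles (EVs) that were separated on a sucrose gradient and treated with micrococcal nuclease. Libraries were made by template switching with a reverse transcriptase of the group II intron type. The labels' protocols state rRNA depletion for whole-cell RNA and state nothing on it for EV RNA. Each genotype and compartment has 1 library, so there were no replicates.

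The authors deposited 1 table of estimated counts per row (expected read counts as Salmon gives), not scaled between libraries. Per the submitters' processing notes, cutadapt, UMI-tools, Novoalign and Salmon were used with the mouse builds GRCm38 and mm10. The tools' versions, the order of the steps and whether reads were deduplicated are not given in the sources used here. The table has 580839 rows. Of these, 3894 stand for whole RNAs: 3639 Ensembl transcripts, 224 tRNA genes in 51 anticodon families, 15 spliced tRNAs, 15 SINE rows and 1 row for 4.5S RNA. The other rows are exon, intron and UTR pieces of transcripts. Of the 3639 transcripts, 3634 stand again as UTR pieces with 93.3% to 98.0% of the counts, so the sets overlap. They were summed only for totals and shares of all rows, which count some RNAs more than once. Within the whole-RNA rows, 8 SINE rows have the same counts in all 7 libraries as a transcript row and were kept in both kinds; all SINE rows together held at most 0.241% of a library. The 3894 whole-RNA rows were used for all comparisons, and their totals were taken as depth. Exon, intron and UTR pieces served in alternatives and in the closing section.

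The table does not pair transcript IDs with gene names, and 0 of 3639 IDs were matched to one. The lists fixed by gene symbol were therefore not matched and have no result: known Dis3l2 substrates, interferon-stimulated and NF-kB genes, stress genes, RNA decay machinery, RNA sensors, histones, ribosomal proteins, mitochondrial mRNAs, EV genes, immediate early genes and cell type markers. The lists of tRNA, SINE, 4.5S and transcript rows were usable. These classes follow the row names. Transcript rows carry no RNA type and may include tRNAs that are not named as such, so tRNA counts and shares cover named tRNA rows only. Lists of spliced tRNAs and of the 24 unspliced tRNA rows in the 4 families with an intron (Arg-TCT, Ile-TAT, Leu-CAA and Tyr-GTA) were added after the data were examined. No row is named as rRNA, so none was left out.

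Single libraries were compared as log2 ratios of scaled counts, with an exact conditional binomial 95% interval. Estimated counts were rounded to whole numbers for intervals and fits. A row passed the rule of size with at least 100 counts over both libraries, a ratio of at least 2 either way and an interval that excluded 1. Knockdown, rescue and mutant pairs were scaled by TMM (trimmed mean of M values), and EV against cell pairs by the totals of the whole-RNA rows. List medians used members with at least 20 counts and were placed among 10000 random lists matched on expression. Fits over groups used edgeR 4.0.16 quasi-likelihood tests with filterByExpr and a Benjamini-Hochberg adjusted p threshold of 0.05. One fit set the 3 EV libraries classed as without active Dis3l2 (shDis3l2, Vector and D389N) against the 2 classed as with it (shNS and Dis3l2r). It used TMM and had 3 residual degrees of freedom. The other set the 5 EV against the 2 whole-cell libraries with Dis3l2 class as a covariate, unscaled totals and 4 residual degrees of freedom. As an alternative it was run on the 4 parental libraries alone, where the Dis3l2 class is the line, so that EVs and cells were compared within shNS and within shDis3l2 (470 of 604 RNAs called). The libraries of a class are different genotypes and not replicates. The class was assigned from the genotype in each title, and no title states Dis3l2 activity. Wherever the text or a caption says with or without active Dis3l2, this assigned class is meant. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Shares of counts have exact (Clopper-Pearson) binomial 95% intervals.

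The rule for names took the 5 largest rises and falls among RNAs with a name past the rule of size in each pair, the 10 smallest adjusted p each way in the fit on Dis3l2 class, and list members with at least 20 counts. In the D389N pair the RNAs named for the rescue were followed. At most 2 transcript IDs higher and 2 lower are printed. Groups, comparisons, the rule of size, lists by symbol and most alternatives were chosen before the data were examined. The set of whole-RNA rows, the families and the D389N against Dis3l2r and Vector against shDis3l2 pairs were fixed afterwards.

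Alternatives were other scalings (DESeq2 size factors, totals, totals of all rows, totals without the transcript that was most abundant in whole cells, exon-piece totals), count minimums of 20 and 500, DESeq2 and limma-voom tests, a term for line set, other filters, each library left out, UTR or exon pieces, and sums per anticodon. Data were simulated with the spread of these libraries. For the fit on Dis3l2 class, 200 of 575 RNAs were changed. It found 12% of RNAs changed 2-fold and 64% of those changed 4-fold, with 1 false call among the unchanged RNAs. The EV against cell fit found 7% and 44%, with 4 false calls. Pairs were simulated with counting error only, 4-fold changes, high expected counts and a known scale. In them all 48 changed rows were found, with 0 false calls, and intervals held the true ratio in 97.3% of rows. This checks the calculation and gives no rate of false calls at the spread between libraries. Intervals cover counting error only, and adjusted p-values measure only the spread between these libraries.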

Results

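RNA of RAW264.7 macrophages and of the extracellular vesicles (EVs) they release was sequenced after knockdown of Dis3l2, a 3' to 5' exoribonuclease that degrades uridylated RNA. Whole-cell RNA was read from cells with a control hairpin (shNS) and with a hairpin against Dis3l2 (shDis3l2), both with doxycycline. EV RNA was read from the same lines and from shDis3l2 cells that carried an empty vector (Vector), a Dis3l2 transgene (Dis3l2r) or Dis3l2 with the D389N change in its catalytic site. Each of the 7 groups had 1 library. Counts on whole-RNA rows came to 37041326 and 32342600 in the shNS and shDis3l2 cells. In EVs they came to 23667929 for shNS, 18428621 for shDis3l2, 25177102 for Vector, 13439408 for Dis3l2r and 20950531 for D389N. CPM stands for counts scaled to that total. Knockdown and re-expression of Dis3l2 itself could not be checked, because the table does not pair transcript IDs with gene names. Across 553 RNAs, which are not independent replicates, log2 CPM correlated at r between 0.975 and 0.984 among EV libraries, at 0.958 between the cell libraries, and between 0.393 and 0.489 across compartments.

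The first comparison asked which RNAs are found in EVs. tRNA made up most whole-RNA counts of EVs: tRNA and spliced tRNA rows held 75.04% of shNS EV counts (95% interval 75.02% to 75.06%) and 13.7% of shNS cell counts. The share lay between 70.2% and 76.9% in all 5 EV libraries and was 9.09% in shDis3l2 cells; as a share of all rows, overlapping pieces included, it was 38.0% to 46.9% in EVs and 6.98% and 4.37% in cells. The 4.5S RNA, a short RNA polymerase III transcript of rodents, held 4.78% to 8.30% of EV counts, against 0.195% and 0.0865% in the 2 cell libraries. Transcript rows showed the reverse, with 86.1% and 90.8% of counts in cells and 16.6% to 24.5% in EVs. Their RNA types are not given and they may include tRNAs, so the tRNA shares here cover named tRNA rows only.

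**Figure D1:**
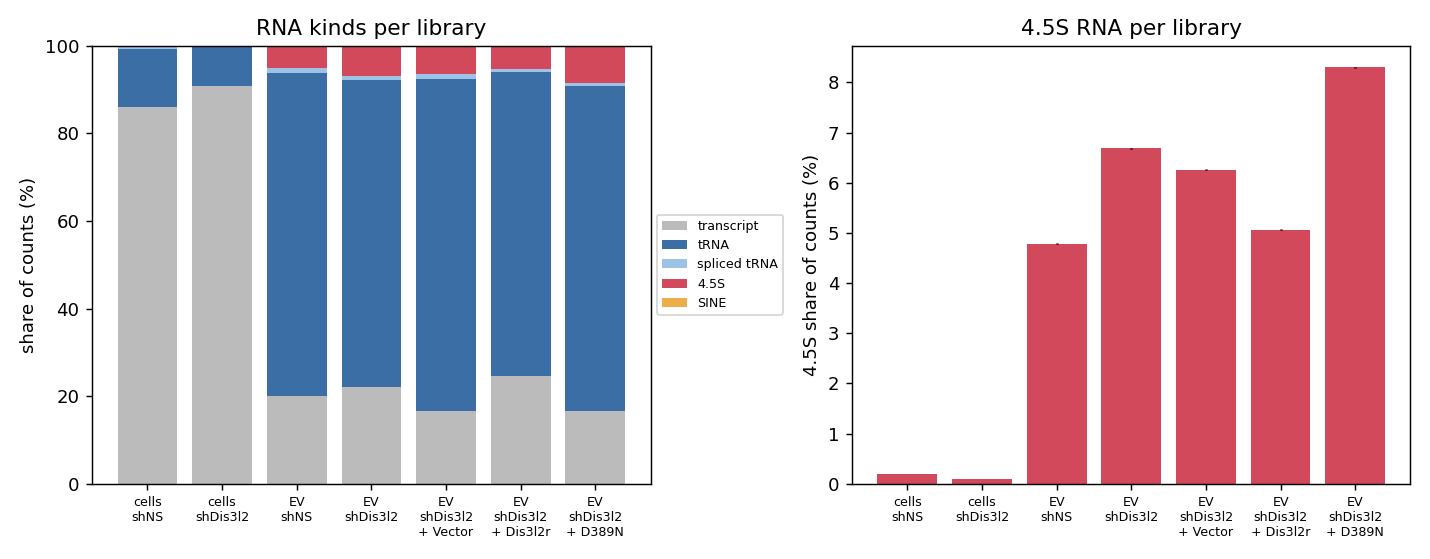
Left, the share of whole-RNA counts (percent) in each RNA class for each of the 7 libraries as stacked bars; right, the share of 4.5S RNA (percent) with exact binomial 95% intervals. tRNA and spliced tRNA held 70.2% to 76.9% of counts in EVs, and 4.5S RNA lay between 6.26% and 8.30% in the 3 EV libraries without active Dis3l2 and at 4.78% and 5.06% in the other 2.

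Among single RNAs of shNS EVs against shNS cells, 170 were higher and 316 lower by the rule of size (at least 2-fold, interval excluding 1), of 531 measured. Of 164 tRNA rows, 128 were higher and 13 lower. By anticodon, 42 of 49 families were higher and 4 lower (43 and 0 with DESeq2 size factors, 1 and 45 with exon-piece totals). The most abundant tRNA of EVs, tRNA-Gly-TCC-1-1, was higher by a log2 ratio of 4.03 (4.03 to 4.04), and tRNA-Ile-AAT-3-1 by 9.20 (8.51 to 10.13), while tRNA-Ser-GGA-1-1 was higher by 6.08 (5.42 to 6.94). tRNA-His-GTG-3-1 had 353 counts in EVs and 1 in cells, a log2 ratio of 8.53 (6.62 to 14.42), against 4.96 (4.08 to 6.19) with 9 cell counts in shDis3l2. SINEs, short interspersed repeats transcribed by RNA polymerase III, were higher in 6 of 6 measured rows, among them both rows of SINE_B1_Mus2 at 5.77 (5.58 to 5.96) and 6.34 (6.21 to 6.48). Of 13 SINE rows with at least 20 counts, 8 have the counts of a transcript row in all 7 libraries, both SINE_B1_Mus2 rows among them, so those RNAs stand in both lists. SINE_B4 had 108 counts in EVs and 1 in cells (6.82, 4.89 to 12.72), against 2.25 (1.72 to 2.84) with 38 cell counts in shDis3l2. The shNS cell library had 484 transcript rows above 0, against 662 in shDis3l2 cells. SINE_B2 stood at 2.01 (1.93 to 2.10). Of 346 transcript rows, whose RNA types are not given, 303 were lower, including ENSMUST00000082391 at -9.21 (-9.27 to -9.15).

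Of the 13 tRNA rows that were lower in shNS EVs, 9 were unspliced rows of families with an intron, while 4 other rows of those families were higher. Unspliced Tyr-GTA, Leu-CAA and Ile-TAT were lower as families, at log2 ratios of -1.64, -1.52 and -1.40, whereas the fourth, unspliced Arg-TCT, was higher at 2.74 (2.62 to 2.86). Gly-ACC, a family without a spliced row, was lower at -1.73. The lowest single rows were tRNA-Leu-CAA-4-1 at -3.63 (-3.72 to -3.53), tRNA-Tyr-GTA-4-1 at -3.58 (-3.91 to -3.29), tRNA-Tyr-GTA-1-4 at -3.34 (-3.48 to -3.20), tRNA-Tyr-GTA-1-2 at -3.29 (-4.20 to -2.58) and tRNA-Tyr-GTA-3-2 at -3.06 (-3.19 to -2.93). Of 14 spliced tRNA rows, 7 were higher and 0 lower. List medians were 1.99 for tRNAs (percentile 100 among matched random lists), 1.17 for spliced tRNAs (96.3), -0.74 for intron-containing tRNAs (90.8), 5.42 for SINEs (99.9) and -5.56 for transcripts. The negative median of intron-containing tRNAs turned to 0.35 with DESeq2 size factors. Scaling to exon-piece totals moved the median of all RNAs by -4.48, left 13 higher and 480 lower, and put the medians of tRNAs and spliced tRNAs at -2.49 and -3.32, tRNA-Gly-TCC-1-1 at -0.45 and SINE_B2 at -2.47. The shNS cell library had 27300 exon-piece counts against 555760 in shDis3l2 cells.

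**Figure D2:**
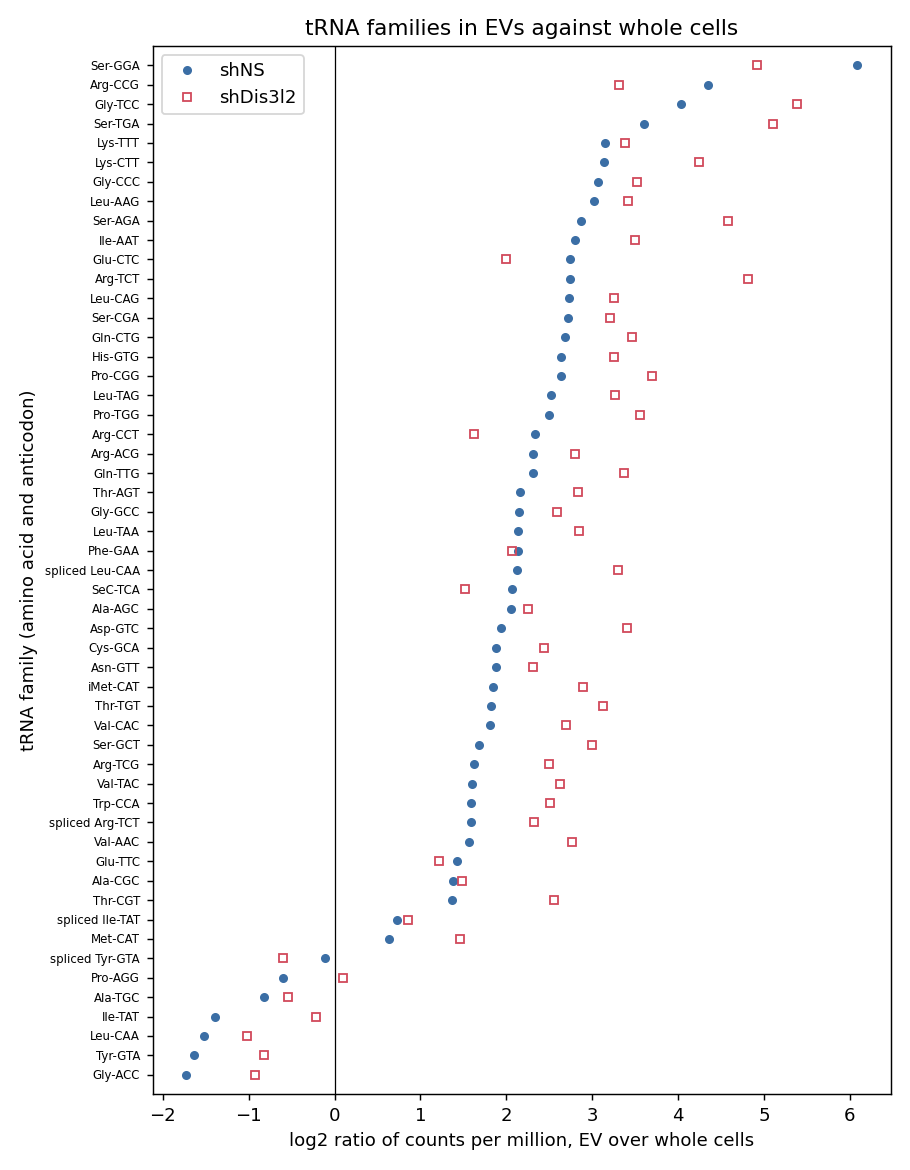
Each row is a tRNA anticodon family, and the horizontal axis gives the log2 ratio of EV over whole-cell counts, with filled circles for shNS and open squares for shDis3l2. Of 49 families, 42 were higher and 4 lower in shNS by the rule of size with whole-RNA totals. Unspliced Tyr-GTA, Leu-CAA and Ile-TAT were among the 4. With exon-piece totals, which are small in shNS cells, the median of tRNA rows in shNS was -2.49.

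EVs of knockdown cells against knockdown cells gave 174 RNAs higher and 305 lower of 525. Of 163 tRNA rows, 134 were higher and 8 lower, and 43 families were higher with Leu-CAA alone lower, at -1.02. tRNA-Gly-TCC-1-1 stood at 5.38, 4.5S RNA at 6.27 (4.62 in shNS), tRNA-Ile-AAT-3-1 at 10.88 and ENSMUST00000082391 at -6.54. SINEs were higher in 6 measured rows. List medians were 2.67 for tRNAs (percentile 100), 1.81 for spliced tRNAs (93.0), 0.09 for intron-containing tRNAs (94.4), 2.11 for SINEs (96.9; 4.12 over the 6 rows with at least 100 counts) and -5.50 for transcripts. The median of intron-containing tRNAs was -0.39 with TMM and -0.75 without the most abundant cell transcript, which held 46.1% of shDis3l2 cell counts. Without that transcript, 113 tRNA rows were higher and 15 lower, and 38 families were higher and 5 lower. The tRNA median was then 1.83, against 1.76 in shNS with the same scaling. 4.5S RNA then stood at 5.43, against 4.38 in shNS. Whether the shift differed between shNS and shDis3l2 was not tested.

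Over all libraries, 5 EV against 2 whole-cell, edgeR called 506 of 642 RNAs at an adjusted p under the threshold, 200 higher and 306 lower in EVs. Among 197 tRNAs 142 were higher and 8 lower, and the counts adjusted over the list alone were the same. Their median log2 fold change was 2.31 (camera adjusted p = 2.5e-37; adjusted p = 0.0388 with an estimated correlation). The 4.5S RNA was higher by 5.45 (SE 0.608, adjusted p = 3.44e-06), tRNA-Ile-AAT-3-1 by 10.82 (SE 0.997, adjusted p = 5.67e-07), tRNA-Gly-TCC-1-1 by 4.48 (SE 0.556, adjusted p = 9.1e-06) and the first SINE_B1_Mus2 row by 5.55 (SE 0.585, adjusted p = 2.01e-06), whereas tRNA-Leu-CAA-4-1 was lower by -3.18 (SE 0.430, adjusted p = 1.94e-05). SINEs were higher in 7 of 12 rows, with a median of 3.29 (adjusted p = 0.00152; adjusted p = 0.293 with an estimated correlation). Spliced tRNAs had 7 rows higher and 1 lower of 14 and a median of 1.03 (adjusted p = 0.0204; adjusted p = 0.566 with an estimated correlation). Intron-containing tRNAs had 5 higher and 7 lower of 22, with a median of -0.25 and a mean of 0.08 (adjusted p = 0.577). Transcripts had 43 higher and 297 lower of 418, with a median of -5.48 (adjusted p = 0.02 with an estimated correlation). Fry gave unadjusted p = 0.000618 for tRNAs, 0.0029 for SINEs and 2.73e-05 for transcripts. It gave 0.0796 for spliced tRNAs and 0.146 for intron-containing tRNAs. With exon-piece totals 318 RNAs were called, 6 higher and 312 lower. These totals are small in shNS cells, at 0.0375% of the counts of all rows, against 0.713% to 1.23% in the other libraries.

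The next comparison asked what loss of Dis3l2 did to cell RNA. Knockdown cells held more of 1 transcript, ENSMUST00000083988, which went from 19.3% to 46.1% of whole-RNA counts, a log2 ratio of 1.52 (1.52 to 1.52), and less of another, ENSMUST00000082391, at -1.76 (-1.77 to -1.76). 4.5S RNA stood at -0.91 (-0.93 to -0.89), inside the 2-fold rule. SINE_B1_Mus2 was higher in both rows, at 1.22 (0.99 to 1.46) and 1.55 (1.39 to 1.71). Of SINE rows with enough counts for the list, 9 of 9 were above 0 (median 2.28, percentile 98.1). Over the 3 rows with at least 100 counts the median was 1.22. Some rows had few counts in shNS cells, such as SINE_B1_Mur4 (0, against 48 in shDis3l2 cells) and SINE_B4 (1, against 38). The shNS cell library also had fewer transcript rows above 0, 484 against 662. At a minimum of 20 counts, 90 RNAs of all kinds were higher and 133 lower. tRNAs went both ways, with 7 higher and 28 lower of 151 (4 and 54 with totals, 3 and 63 with totals of all rows, 9 and 11 without ENSMUST00000083988).

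The largest tRNA rises in knockdown cells were tRNA-Gly-CCC-2-1 at 2.98 (2.53 to 3.49), tRNA-Arg-CCG-3-1 at 1.56 (1.55 to 1.57), tRNA-Arg-CCT-4-1 at 1.38 (1.37 to 1.40) and tRNA-Ala-AGC-8-1 at 1.32 (0.85 to 1.81). The largest falls were tRNA-Arg-TCT-5-1 at -2.54 (-3.30 to -1.91), tRNA-Trp-CCA-1-1 at -2.32 (-3.28 to -1.55), spliced tRNA-Arg-TCT-5-1 at -1.99 (-2.17 to -1.82), tRNA-Gln-TTG-1-1 at -1.74 (-1.78 to -1.69) and tRNA-Arg-TCG-1-1 at -1.64 (-1.69 to -1.59). By anticodon, Arg-CCG (1.17) and Arg-CCT (1.096) were higher and 8 families lower, the lowest being Gln-TTG at -1.31 and Val-CAC at -1.17; with totals 0 were higher and 20 lower, and without the most abundant transcript 2 and 0. List medians were -0.41 for tRNAs (percentile 0.31; -0.098 without the most abundant cell transcript), -0.56 for spliced tRNAs (29.9) and -0.05 for intron-containing tRNAs (50.9), the last at 0.27 without that transcript. In all, 60 of 513 RNAs were higher and 123 lower. The split followed the scaling: 33 and 179 with totals, 28 and 195 with totals of all rows, and 108 and 74 without the most abundant transcript, which moved the median of all RNAs by -0.27, -0.35 and 0.32 (log2). With exon-piece totals, which are small in shNS cells, it was 1 and 511, at a shift of -4.81, and every RNA named here as higher was below 0. No test was possible with 1 library a side.

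Loss of Dis3l2 in EVs was asked next. Of the unspliced tRNAs of families with an intron, a list added after the data were examined, 19 of 21 rows lay above 0 in knockdown EVs, with a median log2 ratio of 0.64 (percentile 99.8). By the rule 4 of 20 measured rows were higher and 0 lower, and 2 and 1 with totals of all rows or without the most abundant cell transcript. Families Ile-TAT at 1.11 (1.08 to 1.14) and Arg-TCT at 1.04 passed the rule, with Tyr-GTA at 0.70 and Leu-CAA at 0.21. Arg-TCT came to 0.97 with DESeq2 size factors and 0.95 with totals, and with totals of all rows Ile-TAT stood at 0.96 and 0 families passed. 4.5S RNA stood at 0.58 (0.57 to 0.58), and ENSMUST00000174924 was higher at 2.02 (2.02 to 2.03), from 15470 to 58900 CPM; the other EV libraries without active Dis3l2 held 12680 (Vector) and 7046 CPM (D389N), and Dis3l2r EVs 12180. tRNAs as a whole had a median of -0.02 (percentile 20.2), spliced tRNAs of -0.18 (8.4) and SINEs of 0.02 (52.4; between -0.13 and -0.01 with other scalings, and 0.53 over the 7 rows with at least 100 counts, 6 of them above 0).

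Among single tRNAs of knockdown EVs, 10 of 166 were higher and 2 lower. tRNA-Thr-AGT-7-1 had 765 counts against 33 (4.97, 4.49 to 5.54), followed by tRNA-Leu-AAG-2-1 at 2.18 (1.79 to 2.60), tRNA-Lys-TTT-5-1 at 1.51 (1.35 to 1.66), tRNA-Ala-TGC-5-1 at 1.42 (0.83 to 2.06) and tRNA-Ile-TAT-1-1 at 1.23 (1.19 to 1.27). The falls were tRNA-Trp-CCA-1-1 at -1.91 (-2.58 to -1.33) and tRNA-iMet-CAT-3-1 at -1.20 (-1.83 to -0.64). ENSMUST00000083988, higher in knockdown cells, stood at -0.54 in EVs. Altogether 29 of 411 RNAs were higher and 17 lower; at a minimum of 20 counts 57 were higher and 73 lower, and at 500 counts 16 and 4. The split was 23 and 21 with totals, 21 and 23 with totals of all rows, and 21 and 22 without the most abundant cell transcript; the last pair of scalings moved the median of all RNAs by -0.15 and -0.12. These 46 RNAs made 11.2% of those measured. Pairs without change were simulated at the spread of the EV libraries. They measured a median of 398 RNAs at 100 counts, of which 26% (21.9% to 30.2%) differed at least 2-fold. That spread was fitted across the 5 EV libraries and so holds differences between genotypes. The simulated rule used totals and the 2-fold limit without the interval. The simulated share therefore cannot show whether knockdown changed EV RNA. As a yardstick, Vector was set against shDis3l2 EVs, both classed as without active Dis3l2. This gave 35 higher and 59 lower of 393 (46 and 49 with DESeq2 size factors, 67 and 26 with exon-piece totals). The tRNA median was 0.36 (percentile 100).

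**Figure D3:**
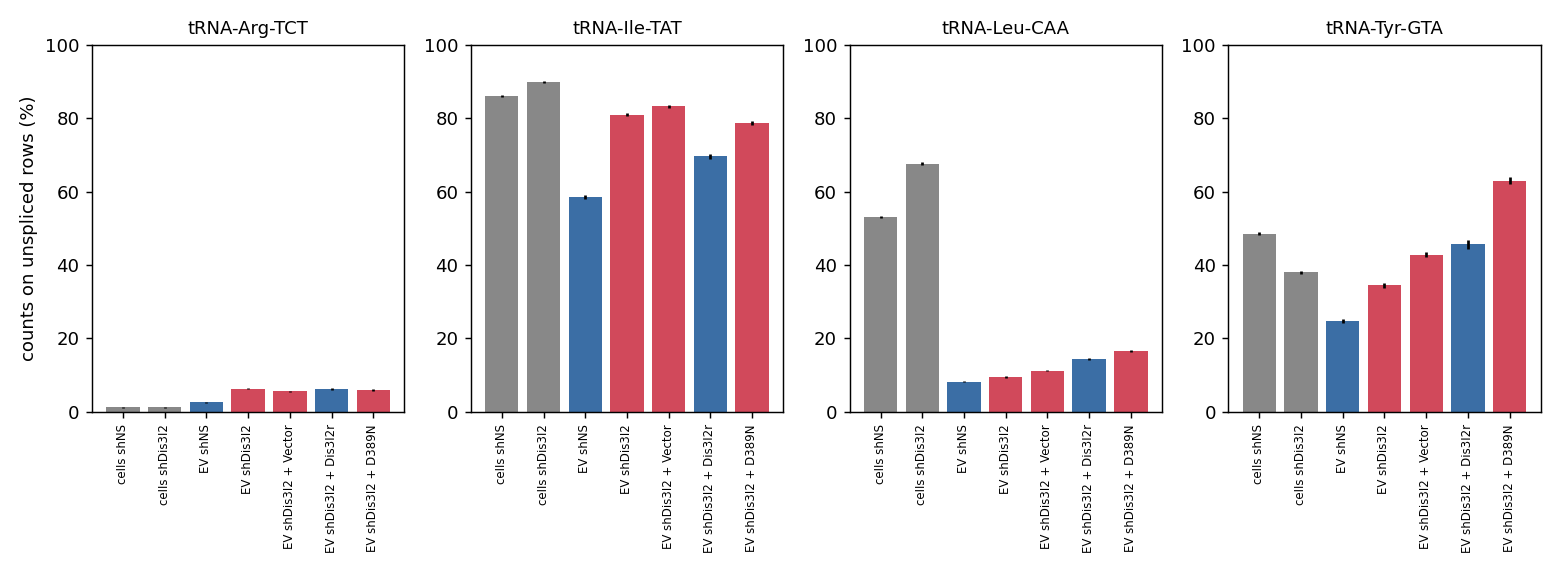
The share of unspliced rows (percent) in all counts of each of the 4 tRNA families with an intron, for each library, with exact binomial 95% intervals as black lines. Grey bars are whole cells, blue bars EVs classed as with active Dis3l2 and red bars EVs classed as without it. The shDis3l2 EVs lay above shNS EVs in 4 of 4 families. Dis3l2r lay below Vector in Ile-TAT (69.6% and 83.2%) but above it in Arg-TCT (6.10% and 5.59%), Leu-CAA (14.4% and 11.2%) and Tyr-GTA (45.6% and 42.8%).

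Restoring Dis3l2 was compared with the empty vector. In EVs with Dis3l2r, tRNAs were mostly lower, with 144 of 190 rows below 0, a median of -0.40 (percentile 0.0), and 25 of 166 lower and 1 higher by the rule (42 lower with DESeq2 size factors, 14 without the most abundant cell transcript, 119 with exon-piece totals). Intron-containing tRNAs had a median of -0.64 (20 of 22 below 0, percentile 0.02), and Ile-TAT stood at -0.97 (-0.996 to -0.934). 4.5S RNA stood at -0.38 (-0.38 to -0.37). Transcripts went the other way, with 94 of 204 higher and 3 lower, among them ENSMUST00000083988 at 1.92 (1.92 to 1.93); with exon-piece totals 25 were higher and 33 lower. The Vector library itself differed from shDis3l2 EVs in the opposite direction, with 57 of 202 transcripts lower and 8 higher (median -0.61) and tRNAs at a median of 0.36.

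Families past the rule were all lower with Dis3l2r: Ser-GGA at -1.96, Arg-TCG at -1.17, Ser-AGA at -1.06 and Val-AAC at -1.05. With DESeq2 size factors 11 families were lower, and with totals or without the most abundant cell transcript 2. Single falls were tRNA-His-GTG-3-1 at -2.66 (-3.15 to -2.23), tRNA-Thr-AGT-7-1 at -2.37 (-2.67 to -2.09), tRNA-Ser-GGA-1-1 at -1.96 (-2.22 to -1.72), tRNA-Ala-AGC-8-1 at -1.94 (-2.04 to -1.84) and tRNA-Val-AAC-1-1 at -1.77 (-1.93 to -1.61). The named rises were SINE_B1_Mm at 2.46 (1.81 to 3.19), SINE_B1_Mur4 at 1.15 (0.61 to 1.69) and tRNA-His-GTG-1-1 at 1.14 (0.92 to 1.35). SINEs had a median of 0.35 (33.6; -0.54 with exon-piece totals) and spliced tRNAs of -0.61 (5.03). The counts were 97 higher and 29 lower of 393, with 82 and 55 by DESeq2 size factors and 111 and 16 without the most abundant cell transcript, which moved the median of all RNAs by -0.22 and 0.16. Exon-piece totals turned the split to 26 and 167, at a shift of -0.89, and a minimum of 500 counts gave 32 and 25. The 126 RNAs past the rule were 32.1% of those measured, against 25.5% (21.9% to 29.5%) of those measured in simulated pairs. Those pairs were built as for knockdown EVs and cannot show whether Dis3l2r changed EV RNA.

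The catalytically inactive protein was compared with the same empty vector. With D389N, 4.5S RNA stood at 0.66 (0.66 to 0.67), opposite in sign to Dis3l2r. tRNA-Thr-AGT-7-1 at -2.58 (-2.86 to -2.31), tRNA-His-GTG-3-1 at -1.65 (-1.96 to -1.36) and tRNA-Val-AAC-1-1 at -1.46 (-1.60 to -1.33) were lower, as with Dis3l2r. tRNA-Ala-AGC-8-1 at -0.57, tRNA-Ser-GGA-1-1 at -0.66 and tRNA-His-GTG-1-1 at -0.62 stayed inside the rule, and SINE_B1_Mm (1.59) and SINE_B1_Mur4 (-0.63) had too few counts for it. ENSMUST00000083988 stood at 0.93 (0.92 to 0.93), inside the rule and in the direction seen with Dis3l2r, and transcripts had a median of 0.34 with 205 of 330 above 0 (-0.09 with exon-piece totals). Families Ser-TGA (1.63), SeC-TCA (1.27), Cys-GCA (1.15) and Leu-CAG (1.14) were higher, and Arg-TCG (-1.16) and Val-CAC (-1.02) lower; with totals, Cys-GCA (0.89) and Leu-CAG (0.89) no longer passed, and with totals of all rows SeC-TCA (0.96) did not either.

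With D389N, 12 of 171 tRNAs were higher and 28 lower, and 0 of 14 spliced tRNA rows lay above 0 (median -0.55, percentile 5.36). Medians were -0.15 for tRNAs (0.06), -0.40 for intron-containing tRNAs (5.52) and 0.93 for SINEs (98.6; 0.50 over the 6 rows with at least 100 counts). In total 41 of 379 RNAs were higher and 47 lower, with 26 and 68 by totals, 21 and 78 by totals of all rows and 26 and 67 without the most abundant cell transcript, which moved the median of all RNAs by -0.25, -0.31 and -0.24, and 16 and 93 by exon-piece totals, at -0.42. At a minimum of 20 counts the split was 101 and 80, and at 500 counts 17 and 32. The 88 RNAs were 23.2% of those measured, against 26% (22.3% to 30.4%) of a median of 407.5 in simulated pairs. Those pairs, built as for knockdown EVs, cannot show whether D389N changed EV RNA. Against Dis3l2r directly, D389N EVs had 10 RNAs higher and 83 lower of 379 (17 and 64 with DESeq2 size factors; 73 and 36, the opposite direction, with exon-piece totals, at a shift of 0.56; 49 and 141 at a minimum of 20 counts), and medians of 0.26 for tRNAs (100), 0.10 for intron-containing tRNAs (98.7), 0.30 for SINEs (98.1) and -0.08 for spliced tRNAs (24.9; 0.09 with DESeq2 size factors). The first 3 turned to -0.05, -0.21 and -0.01 without the most abundant cell transcript.

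The last comparison pooled EV libraries by the Dis3l2 class assigned from the genotype, 3 without active Dis3l2 and 2 with it. Dis3l2 activity itself could not be checked. ENSMUST00000082807 was lower without active Dis3l2: it had 111 counts in shNS and 105 in Dis3l2r EVs, 1 in shDis3l2 EVs and 0 in Vector and D389N EVs. Scaled by depth, the 216 counts with and 1 without active Dis3l2 made a ratio of 376, with a counting interval of 66.7 to 1.49e+04, and Dis3l2r EVs held at least 65.7-fold more than Vector and at least 54.6-fold more than D389N EVs, at a floor of 3 counts per library. Cells showed the same direction, with 1617 counts in shNS and 45 in shDis3l2 (log2 ratio -4.69, -5.17 to -4.28). It was the only 1 of 575 RNAs called by edgeR (adjusted p = 0.00406, lower in 3 of 3 libraries), and 34 had an unadjusted p under 0.05.

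Other RNAs did not pass the adjusted threshold between Dis3l2 classes with the edgeR test chosen before the data were examined. tRNA-Ala-AGC-8-1 had a log2 fold change of 1.62 (SE 0.466, adjusted p = 0.425), tRNA-Thr-AGT-7-1 of 2.86 (SE 0.849, adjusted p = 0.425), tRNA-Ile-TAT-1-1 of 1.16 (SE 0.425, adjusted p = 0.669), tRNA-Val-AAC-1-1 of 1.19 (SE 0.520, adjusted p = 0.669), 4.5S RNA of 0.79 (SE 0.344, adjusted p = 0.669) and tRNA-His-GTG-1-1 of -0.99 (SE 0.449, adjusted p = 0.669). tRNA-Thr-AGT-7-1 was called in 3 of 13 alternatives, with a line-set term (2.97, adjusted p = 0.000173), without a filter (2.79, adjusted p = 0.00167) and without the D389N library (3.34, adjusted p = 0.0146), and its adjusted p ran up to 0.967. tRNA-Ala-AGC-8-1 was called in 1, with DESeq2 (1.65, adjusted p = 0.0361), and also ran up to 0.967. As shares of each library, 4.5S RNA was at 6.69%, 6.26% and 8.30% without active Dis3l2 and at 4.78% and 5.06% with it. tRNA-Ile-TAT-1-1 stood at 879.4, 881.2 and 491.2 CPM without and at 400.5 and 380.6 with it. The classes overlapped for tRNA-Thr-AGT-7-1, at 41.5, 41.6 and 5.82 CPM without (the last in D389N) and 1.39 and 8.41 with it. They also overlapped for tRNA-Val-AAC-1-1, at 62.7, 86.9 and 26.4 CPM without and 32.2 and 26.8 with it. They did not overlap for tRNA-Ala-AGC-8-1 and tRNA-His-GTG-1-1.

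tRNAs as a list had 162 of 196 rows above 0 without active Dis3l2, with a median of 0.34, 0 called and 0 called when adjusted over the list alone (camera adjusted p = 1.28e-14; adjusted p = 0.119 with an estimated correlation). Intron-containing tRNAs had 19 of 22 above 0 and a median of 0.65 (adjusted p = 5.75e-06; adjusted p = 0.119 with an estimated correlation), and transcripts a median of -0.33 (adjusted p = 6.85e-15; adjusted p = 0.119 with an estimated correlation). Spliced tRNAs at 0.06 and SINEs at 0.38 did not pass (adjusted p = 0.498 for both). Fry gave unadjusted p = 0.0438 for intron-containing tRNAs, a list added after the data were examined. For tRNAs it gave 0.182, for transcripts 0.181, for spliced tRNAs 0.94 and for SINEs 0.789. ENSMUST00000082807 kept a log2 fold change between -9.96 and -6.24 over the 13 alternatives that fitted it, and 9 of them called it. Its adjusted p, which ran from 3.37e-08 to 0.581, missed the threshold without the Vector library (0.198), without the Dis3l2r library (0.0612), with limma-voom (0.178) and with UTR pieces (0.581), and a minimum mean of 50 counts left it untested.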

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

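All tests of explanations here were chosen after the results were seen. Some ratios of knockdown over control had opposite signs in cells and EVs, and none of these differences was tested. 4.5S RNA, within the 2-fold rule in both, stood at -0.91 in cells and 0.58 in EVs (log2), the sum of tRNA rows at -0.32 in cells and 0.015 in EVs (between -0.67 and -0.01 in cells and between -0.13 and -0.06 in EVs, so not opposite, with totals, totals of all rows, DESeq2 size factors or without the largest cell transcript), and 6 RNAs passed the rule of size in opposite directions. For these, independent calls would give 5.1 and 2.0 by chance, against 3 and 3 observed, so there is no excess of opposite calls; in the same direction 2.9 and 3.5 would be given, against 6 and 6 observed.

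Exon, intron and UTR pieces of transcripts were not used in the main comparisons, and some held a larger share of all counts than in the control library. Exon pieces made 0.0375% of counts in shNS cells and 0.827% in shDis3l2 cells, a ratio of 22.0, and intron pieces stood at a ratio of 1.32. In EVs the ratio for shDis3l2 over shNS was 1.04 for intron and 0.922 for exon pieces. Dis3l2r over Vector gave 1.73 for exon and 1.13 for intron pieces, and D389N over Vector gave 1.08 for exon and 1.08 for intron pieces.

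The gain of exon pieces in knockdown cells, or their shortfall in control cells, was weighed further. shNS cells had the fewest pieces of all libraries. Exon pieces above 0 numbered 6227 there, 19766 in shDis3l2 cells and 11653 to 24547 in EVs. Intron pieces above 0 numbered 19433 in shNS cells, 115493 in shDis3l2 cells and 54657 to 95927 in EVs. With 1 control cell library, a gain and a shortfall cannot be told apart. The tables argue against depth, since the knockdown library had 0.873 times the counts of the control. Of the summed gain, 87.7% lay in 10 transcripts, which had 198 counts in shNS cells, 471682 in shDis3l2 cells and between 37272 and 88658 in EV libraries, so a few transcripts may account for most of it, while the rest still rose 3.1 times. Genomic DNA in the knockdown library, or loss of low-count pieces from the control library, could not be excluded: intron pieces above 0 were 5.94 times as many and exon pieces above 0 were 3.17 times as many. A response of cell RNA to loss of Dis3l2 stays open and untested, with 1 library a side.

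The lower tRNA share in knockdown cells was the second pattern. tRNA and spliced tRNA rows held 13.7% of counts in shNS and 9.09% in shDis3l2 cells, a ratio of 0.663. With ENSMUST00000083988 left out of both libraries the shares were 17.0% and 16.9%, a ratio of 0.991. A candidate explanation for the lower share is therefore the larger share of that 1 transcript, and why the transcript differed was not tested. The fall of single tRNA families relative to others is not addressed by this test.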

How the results depend on the processing

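Totals without the largest cell transcript, exon-piece totals, UTR pieces, exon pieces and anticodon sums were chosen after seeing the data. So were all alternatives for D389N against Dis3l2r and Vector against shDis3l2. The same holds for DESeq2 size factors and the minimum of 20 counts in the EV against cell pairs. Of 85 counts under alternatives, 63 stayed within 1.5 times the main count and 22 moved. This tally ignores direction. Without the largest cell transcript, knockdown cells had 182 past the rule against 183, but the split went from 60 higher and 123 lower to 108 and 74. D389N over Dis3l2r went from 10 and 83 to 73 and 36 with exon-piece totals and was counted as stable. Of 168 list medians 17 stayed nearly the same. A change of sign was seen in 20, 7 of them in lists whose main median lay outside the central 95% of random lists. Of 944 values of single RNAs 593 stayed the same, 317 moved and 16 reversed. In the fits 13 lost and 5 gained their call. Calls lost or gained under the rule of size were not tallied for the pairs. Except where a construction is named, the cause was not tested. A minimum of 20 counts, which admits more RNAs, gave 130 past the rule in shDis3l2 over shNS EVs, 212 for Dis3l2r over Vector, 181 for D389N over Vector and 190 for D389N over Dis3l2r; a minimum of 500, which admits fewer, gave 20, 57, 49 and 34. In the fit on Dis3l2 class, 2 RNAs were called with a line-set term, 2 with DESeq2, 0 with limma-voom, 3 without a filter, 0 at a mean of at least 50 counts, 0 with UTR pieces, 0 with exon pieces (201 of 6745 at an unadjusted p under 0.05), and 0 to 2 with a library left out (0 without Vector, 2 without D389N). tRNA-Trp-CCA-1-1 was 0.014 with the line-set term, and with a library left out it ran from -1.53 to 1.45, tRNA-Val-CAC-1-1 from -0.991 to 0.079 and spliced tRNA-Ile-TAT-2-1 from -0.722 to 0.065, each positive without shNS. Exon-piece totals gave 512 past the rule in knockdown cells and 193 for Dis3l2r over Vector. EV against cells gave 318 calls with exon-piece totals and between 403 and 502 with a library left out (403 without shDis3l2 cells, 440 without shNS cells).

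With exon-piece totals the tRNA median in shNS EVs over cells was -2.49, ENSMUST00000174924 -2.06, tRNA-Gly-TCC-1-1 -0.45 and SINE_B2 -2.47, and SINE_B2 was -0.98 over all libraries. In knockdown cells they put the SINE median at -2.53, tRNA-Gly-CCC-2-1 at -1.83, tRNA-Arg-CCG-3-1 at -3.25, tRNA-Arg-CCT-4-1 at -3.43, tRNA-Ala-AGC-8-1 at -3.49, ENSMUST00000083988 at -3.29, ENSMUST00000174924 at -3.33 and the SINE_B1_Mus2 rows at -3.59 and -3.26. In D389N over Dis3l2r, without the largest cell transcript, medians were -0.046 for tRNAs, -0.213 for intron-containing tRNAs and -0.012 for SINEs; the intron-containing median was -0.136 with totals and -0.021 with totals of all rows. tRNA shares of all rows were 6.98% and 4.37% in shNS and shDis3l2 cells, and 45.8%, 41.7%, 46.9%, 38.0% and 43.8% in shNS, shDis3l2, Vector, Dis3l2r and D389N EVs. As shares of whole-RNA counts without the largest cell transcript they were 17.0%, 16.9%, 79.3%, 73.5%, 78.5%, 76.5% and 77.4%. Not run were rRNA kept in the fit (no row is named as rRNA), protein-coding totals (exon-piece totals took their place) and classes by biotype, which the table does not give. Depth limits rows near 100 counts.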

Other observations

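All tests in this part were chosen after the results were seen. Introns of tRNAs are removed by splicing, and for 4 families the table has rows labelled mature, called spliced here. The other 24 rows of those families were called unspliced by family, without a check that each gene has an intron. How reads that match both kinds of row were assigned is not given. The shares below are therefore shares of rows and not a measured splicing state. Unspliced rows held 52.3% of these families' counts in shNS cells and 59.7% in shDis3l2 cells, but 12.5% (12.4% to 12.6%) in shNS EVs. In EVs the share was 21.5% with shDis3l2, 20.8% (20.7% to 20.9%) with Vector, 21.0% (20.8% to 21.3%) with Dis3l2r and 24.1% with D389N. Tyr-GTA went from 24.7% in shNS to 34.4% in shDis3l2 EVs, Arg-TCT from 2.63% to 6.35%, Ile-TAT from 58.4% to 80.9% and Leu-CAA from 8.24% to 9.49%. Ile-TAT was the family in which Dis3l2r (69.6%) lay below Vector (83.2%) and D389N lay at 78.7%.

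The hypothesis that loss of Dis3l2 may raise the unspliced share in EVs was tested with the rescue. The share was higher with knockdown in 4 of 4 families, by 9.04 percentage points over all 4, but Dis3l2r differed from Vector by 0.232 points and lay below it in 1 of 4 families. D389N lay above Dis3l2r in 3 of 4. With 1 library per genotype, and without a measure of how much Dis3l2 was restored, the rescue does not decide between loss of Dis3l2 and differences between lines or libraries.

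The number of RNAs whose 3 EV libraries without active Dis3l2 all lay above, or all below, both others followed the scaling, and chance gives 10% each way for independent RNAs. With counts scaled to totals 32 of 575 (5.6%) lay all above and 124 (21.6%) all below, and with TMM, as in the fit, 77 (13.4%) and 103 (17.9%). Among transcripts 117 of 352 (33.2%) lay all below and 15 all above with totals, and 98 (27.8%) and 33 with TMM. Among tRNAs 15 of 196 (7.7%) lay all above and 5 all below with totals, and 39 (19.9%) and 3 with TMM. Of the 22 intron-containing tRNAs, 4 lay all above with totals and 11 with TMM, and 0 all below with either.

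The fit on Dis3l2 class called 1 RNA. Of the 10 splits of the 5 EV libraries into 3 and 2, 2 gave as many, the real one included, and the highest other count was 1. The splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 34 RNAs, and 3 of the 9 other splits gave more (93, 49 and 36).

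Log2 ratios of Dis3l2r and D389N over Vector moved together across 399 RNAs (r = 0.565, across RNAs, which are not independent replicates). Of 366 RNAs measured in both, 21 were higher in both (7.4 by chance if independent) and 16 lower in both (3.6), against 1 and 0 in opposite directions. Both ratios share the Vector library, and simulated libraries without change gave r = 0.493 (up to 0.585) and a covariance of 0.453 (0.332 to 0.612). The covariance of 0.677 exceeded the simulated mean by 0.224, so effects common to both transgene lines may add to the shared control, but the single Vector library cannot be split and these cannot be told apart. In pairs without a shared library, shDis3l2 over shNS and Vector over Dis3l2r, r was 0.184 (Spearman's rho 0.141) across 399 RNAs. After centring on the medians, 207 of them (51.9%) had the same sign. Of 378 RNAs measured in the knockdown and rescue pairs, 10 were lower with knockdown and higher with Dis3l2r (3.1 if independent). The reverse held for 5 (1.9), while 2 were higher in both (6.3) and 0 lower in both (0.9). Simulated libraries without change gave r from -0.111 to 0.102. They drew RNAs independently at a spread that holds genotype differences, so r outside this range is not a test. With D389N over Dis3l2r in place of Vector over Dis3l2r, r was 0.098, inside that range, and 227 RNAs (56.9%) had the same sign. Among tRNAs r was 0.168 for the Vector and -0.068 for the D389N pair, and among transcripts 0.313 and 0.213; the range was simulated over all RNAs of the Vector pair, not for these subsets.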
